A study of Phaeocystis antarctica with 15 samples.

How the data were processed

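Cultures of Phaeocystis antarctica strain #25 were grown without added iron at 16:8 h light and dark, 40 µE and 2 ± 2 °C. Per the labels, 4 replicates were held under iron limitation for 48 h before ferric chloride was added, and samples were taken before iron (0 h) and 14 h, 24 h and 72 h after it. About 100 ± 10 ml were filtered on 1.2 µm membranes, and total RNA was extracted with an RNeasy Plant Mini kit. The 15 libraries were assigned to 4 groups by their labels, with 4, 3, 4 and 4 libraries. Per the labels, the same 4 replicates were sampled at each time, and replicate 2 is missing at 14 h. The number of a replicate was taken from this to mark the same culture at each time. In a check of this pairing, residuals of log2 CPM had a mean correlation of 0.075 (-0.093 to 0.287) over 21 pairs of libraries with the same number and -0.025 over 63 pairs with different numbers, and 8 of 15 libraries were closest to one of their own number.

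Per the submitters' processing notes, reads were trimmed with Trimmomatic 0.32 and quantified with RSEM; the assembler, the aligner and their settings are not given in the sources used here. The deposited gene table holds expected counts, estimated reads per assembled gene, of which 6.39% to 9.7% per library were not whole numbers. A deposited table of FPKM, scaled between libraries by TMM factors per its title, had sums of 989277 to 1968540 per library and was used as an alternative only. The deposited annotation gives, for each of 122927 transcripts, the best UniProt match by BLASTx with its E-value, a search score that was at most 1e-05. It described 17664 genes, 15.92% of the 110971 genes, and 252 had several descriptions. A list pairing assembly and archive identifiers was not used here. No reference genome was used.

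Expected counts were rounded and tested in edgeR 4.0.16 under R 4.3.3. Genes were kept by filterByExpr (minimum count 10, minimum total 15), which left 56541. Libraries were scaled by TMM, and 1 quasi-likelihood model with robust estimation and 1 coefficient per group was fitted to all 15 libraries. The common biological coefficient of variation was 0.241. Two-sided tests compared 14 h, 24 h and 72 h with 0 h, 24 h with 14 h, and 72 h with 24 h, and genes with a Benjamini-Hochberg adjusted p under 0.05 were called. The SE of a log2 change is its size divided by the square root of the F statistic. CPM of single genes are TMM-scaled, and those of vitellogenin and other marker genes are per total count of the library. A fold against a group without counts is a bound from a floor of 3 counts over the group, and one against 1 to 3 counts is a ratio with a 95% counting interval. These cover counting error only. Between pairs of replicates the chi-square per degree of freedom of the counts ran from 2.856 to 19.081, so replicates differed by more than counting error.

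Gene lists of pathways, complexes and other possible sources of RNA were defined by words in the descriptions, 31 in all. The 28 with at least 5 tested members were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01 between genes, adjusted over lists within a comparison. Camera with an estimated correlation and fry were run beside it. Fry tests whether a list's genes move on balance 1 way and does not compare them with other genes. A list for dimethylsulfoniopropionate found no match. Tallies with library size alone are given where the majority turned, the median changed sign, or a majority of at least 1.5 to 1 fell below that. Medians of lists are given minus the median of all genes tested, and setting genes at their bounds moved list medians by at most 0.07. Calls shared between comparisons were counted per direction beside the number expected from independent calls, again with the 0 h libraries divided between comparisons, and in simulated unchanged groups.

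The genes to name were set by rule for each comparison with 0 h. They were the 6 largest changes in each direction among called genes with a mean of at least 10 CPM, no overlap between groups and a description naming a protein; in each list, the called member with the smallest p per direction with a mean of at least 5 CPM; and the most abundant member of each of 4 lists of iron genes. Some of these are left out for length. Groups, comparisons, gene and list tests, lists, this rule and all alternatives but 3 were set before the data were seen.

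Alternatives were DESeq2 size factors (RLE), library size alone, no filter on low counts, a filter of at least 1 CPM in 4 libraries, culture number as a block, only the 2 groups compared, a stricter call (adjusted p under 0.001 and at least 4-fold), the Wald test of DESeq2 1.42.0, limma on log2(FPKM + 1) and log2(FPKM + 0.1), and leaving out each library in turn. The procedure was tested on simulated counts with 50 genes changed at each fold. At 4-fold, edgeR called 33 of 50 for 14 h, 43 for 24 h and 41 for 72 h against 0 h (56496, 56506 and 56514 genes tested), and at 2-fold 11, 14 and 11. At 4-fold it called 34 for 24 h against 14 h (56512) and 40 for 72 h against 24 h (56508), and at 2-fold 9 and 9. None was called in the wrong direction, and of unchanged genes 2, 8, 4, 11 and 6 were called in the 5 comparisons in that order. A list shifted 1.5-fold was called in each, and 0 of the 27 others were. This does not cover lists of correlated genes.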

Results

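Gene expression was measured by RNA sequencing in 15 libraries of Phaeocystis antarctica strain #25, a colony-forming haptophyte alga isolated from the Ross Sea. The cultures had been kept short of iron, and ferric chloride was then added to them. Libraries came from 4 cultures before iron (0 h, n = 4) and from the cultures 14 h (n = 3, the cultures numbered 1, 3 and 4), 24 h (n = 4) and 72 h (n = 4) after iron. Total expected counts per library ran from 7668641 to 8659616 at 0 h, 7896226 to 8717573 at 14 h, 6741329 to 8665734 at 24 h and 7761069 to 14410881 at 72 h. The design holds no culture left without iron beyond 0 h, so each comparison with 0 h carries the time in culture along with iron. The 14 h libraries were also taken at another clock time of the 16:8 light and dark cycle than the others. Of 110971 assembled genes, 56541 had enough counts to be tested, and 12556 of these had a protein description. Genes are named here by that description, the best match in a protein database, and by their identifier in the assembly. A description is a likeness in sequence and does not show that the gene has that function in this alga. Genome positions were not used here. Values of a gene are given as mean ± SD of CPM, read counts scaled to the size of the library, over the libraries of a group, and log2 changes as estimate ± SE.

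The 4 groups separated in a principal component analysis of log2 CPM. Component 1, with 48.5% of the variance, ran from -204.1 to -190.9 in the 0 h libraries, from 153.5 to 279.9 at 14 h, from 88.7 to 125.6 at 24 h and from -100.7 to -58.5 at 72 h. Component 2, with 21.2%, set the 0 h and 14 h libraries (92.1 to 129) apart from those of 24 h and 72 h (-125.8 to -61.6). A pair of contigs of 1 assembly cluster, TR39932, chosen for abundance, held 3.29% of the counts at 0 h, 6.39% at 14 h, 13.1% at 24 h and 6.26% at 72 h. Its described member, TR39932:c0_g1, matches Protein TAR1, encoded on the strand opposite to ribosomal RNA genes. Genes with a description held 43.6% of the counts at 0 h and 52.2%, 51.8% and 53.1% at 14 h, 24 h and 72 h. On average 95294.8 genes had at least 1 count at 0 h, against 78162.7, 81009 and 88968.2 at the later times. Each of these 9 differences from 0 h had the smallest p its exact two-sided permutation test can give, 0.02857 for 4 against 4 libraries and 0.05714 for 3 against 4 (Benjamini-Hochberg adjusted, 0.04286 and 0.05714). An exact permutation test exchanging libraries only within numbered cultures gave p = 0.125 for 4 pairs and 0.25 for 3, again its smallest.

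The comparison of 14 h with 0 h asks how expression in the iron-limited alga differed within the first day after iron. Electron carriers of the plastid moved in opposite directions. Flavodoxin (TR4324:c0_g1), the flavin protein that stands in for ferredoxin where iron is short, fell from 1220 ± 90.6 to 21.4 ± 0.488 CPM (log2 change -5.84 ± 0.2). Ferredoxin-2 (TR49266:c0_g4), an iron-sulfur carrier, rose from 7.82 ± 1.61 to 2160 ± 462 CPM (log2 change 8.11 ± 0.2). Plastocyanin (TR49637:c0_g1), a copper protein that can replace cytochrome c6, fell from 1720 ± 160 to 107 ± 6.76 CPM (log2 change -4 ± 0.15). The iron-sulfur subunit of the cytochrome b6-f complex (TR36823:c0_g1) rose from 245 ± 78.7 to 3810 ± 755 CPM (log2 change 3.96 ± 0.21). Among the iron-containing plastid electron carriers 15 of 18 members rose, 2 fell and 1 did not pass (15 and 2 adjusted over the list alone). For the plastid carriers the median was 2.82 relative to all genes (camera adjusted p = 1.71e-05, or adjusted p = 0.334 with an estimated correlation). The gene described as 2Fe-2S ferredoxin (TR29734:c1_g1) went the other way and fell from 15.6 ± 2.16 to 0.646 ± 0.113 CPM (log2 change -4.56 ± 0.3). Rubredoxin (TR3882:c1_g2), another iron protein, rose from 0.307 ± 0.109 to 487 ± 205 CPM (log2 change 10.56 ± 1.34). Both flavodoxin and plastocyanin, the 2 members of the list of iron-sparing carriers, fell. The largest edgeR adjusted p among the genes named so far was 2.89e-05.

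**Figure D1:**
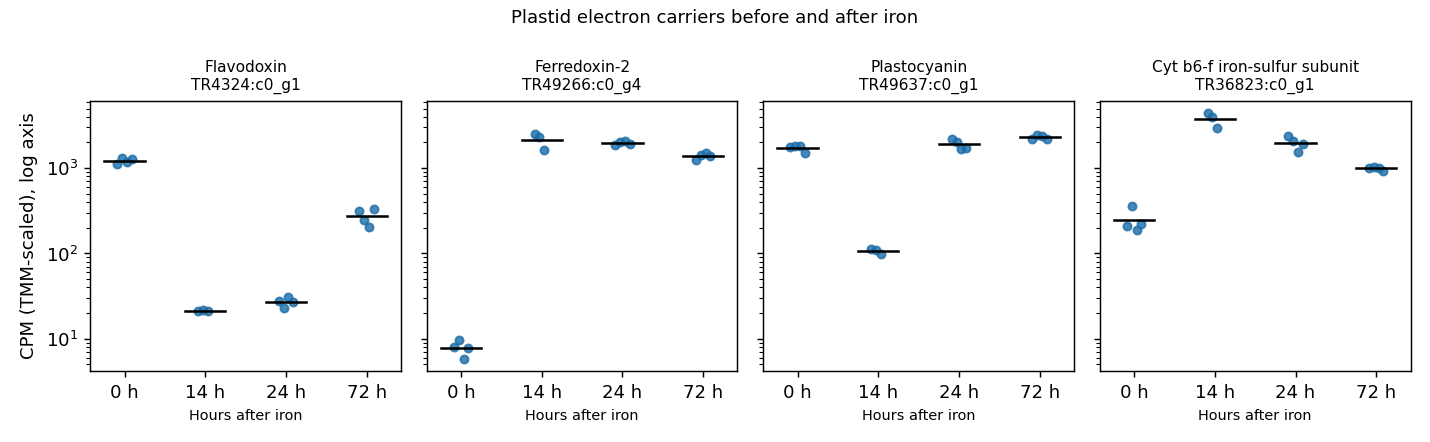
TMM-scaled CPM on a log axis against hours after iron (0, 14, 24 and 72 h) for 4 plastid electron carriers, with 1 point per library and a line at the group mean. Flavodoxin goes from a mean of 1220 at 0 h to 21.4 at 14 h and 275 at 72 h, and ferredoxin-2 from 7.82 to 2160 and 1380.

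Genes for moving and storing iron went both ways at 14 h. Vacuolar iron transporter 1.1 (TR36365:c0_g1), of a family that loads iron into vacuoles, rose from 22.9 ± 4.06 to 369 ± 50.1 CPM (log2 change 4.01 ± 0.16). A multicopper oxidase (TR3087:c10_g1), of a family that holds ferroxidases of high-affinity iron uptake, fell from 48 ± 9.37 to 0.58 ± 0.217 CPM (log2 change -6.29 ± 0.43). Mitoferrin-1 (TR10137:c0_g1), an iron carrier of the inner mitochondrial membrane, had 68.7 ± 9.67 CPM at 0 h and 2 counts over the 14 h libraries, a ratio of 686 with a counting interval of 190 to 5670. On the list for iron uptake, which did not pass, 18 members were tested and 3 rose, 7 fell and 8 did not pass (3 and 7 adjusted over the list alone, camera adjusted p = 0.483). That list's pattern also took in vacuolar transporters and unrelated kinases, and after these were set aside, a step chosen once the members had been seen, 3 of 8 fell and none rose. For iron storage and heme breakdown 5 rose, 4 fell and 4 did not pass (5 and 4 adjusted over the list alone, or 4 higher and 6 lower with library size alone), with a median above 0, a mean of -0.14 and a camera statistic pointing up (adjusted p = 0.598). Assembly of iron-sulfur clusters had 9 higher, 4 lower and 8 that did not pass (9 and 4 adjusted over the list alone, or 6 higher and 7 lower with library size alone). IscA (TR22395:c7_g1), a carrier in that pathway, rose from 3.42 ± 0.834 to 85.6 ± 25.8 CPM (log2 change 4.64 ± 0.22). The cluster assembly list as a whole did not pass (camera adjusted p = 0.0882), and the largest edgeR adjusted p among the genes in this account of iron handling was 7.74e-10.

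Antenna genes had the smallest camera p of the lists at 14 h. In the light-harvesting antenna 66 of 79 members rose, 8 fell and 5 did not pass (66 and 8 adjusted over the list alone). For the antenna the median was 2.83 relative to all genes (camera adjusted p = 1.83e-16, or adjusted p = 0.334 with an estimated correlation). Most of these match fucoxanthin-chlorophyll a-c binding proteins, the main antenna of haptophytes and diatoms. TR53578:c2_g1 rose from 5.72 ± 0.817 to 537 ± 189 CPM (log2 change 6.55 ± 0.23). TR5626:c1_g1 fell from 633 ± 69.4 to 5.01 ± 1.48 CPM (log2 change -6.96 ± 0.21). Another, TR23582:c0_g1, had 1 count over the 0 h libraries and 45.1 ± 27.5 CPM at 14 h, a ratio of 1820 with a counting interval of 326 to 72100. How reads of near-identical copies of any gene were divided among them was not examined. Of the photosystem subunits 23 rose, 1 fell and 4 did not pass (23 and 1 adjusted over the list alone). For the photosystem subunits the median was 2.3 relative to all genes (camera adjusted p = 6.52e-07, or adjusted p = 0.334 with an estimated correlation). Psb27 (TR50484:c7_g1), a lipoprotein of photosystem II assembly, rose from 37.6 ± 3.93 to 711 ± 223 CPM (log2 change 4.24 ± 0.19). The 12 kDa extrinsic protein of photosystem II (TR21098:c0_g1) fell from 21.2 ± 4.41 to 3.89 ± 0.303 CPM (log2 change -2.45 ± 0.24). Neither list of pigment genes passed. For chlorophyll and heme biosynthesis 10 rose, 13 fell and 8 did not pass (10 and 13 adjusted over the list alone, camera adjusted p = 0.591). Protochlorophyllide reductase A (TR7137:c7_g1), an enzyme of chlorophyll synthesis, fell from 314 ± 13.1 to 1.59 ± 1.15 CPM (log2 change -7.54 ± 0.28). For photoprotection and carotenoid synthesis 14 rose, 15 fell and 5 did not pass (14 and 16 adjusted over the list alone, camera adjusted p = 0.871), with a median of 0.11 relative to all genes beside a mean of -0.47. Zeaxanthin epoxidase (TR21334:c0_g1), of the xanthophyll cycle, rose from 2.92 ± 1.21 to 234 ± 32.3 CPM (log2 change 6.32 ± 0.26). 15-cis-zeta-carotene isomerase (TR30920:c0_g1) fell from 62.4 ± 6.4 to 0.255 ± 0.101 CPM (log2 change -7.88 ± 0.27). Every gene named for photosynthesis had an edgeR adjusted p of at most 6.81e-08.

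Within central metabolism single genes with like descriptions moved far in opposite directions. Fructose-bisphosphate aldolase (TR41456:c0_g1), of glycolysis and the Calvin cycle, rose from 2.59 ± 0.982 to 2100 ± 155 CPM (log2 change 9.66 ± 0.23). The cytoplasmic isozyme (TR21400:c0_g1) fell from 472 ± 44 to 16.2 ± 1.31 CPM (log2 change -4.86 ± 0.28). Of 2 genes for ribulose-phosphate 3-epimerase of the Calvin cycle, TR40550:c0_g1 rose from 1.85 ± 0.841 to 1040 ± 176 CPM (log2 change 9.13 ± 0.28). TR16036:c0_g1 fell from 273 ± 20.6 to 1.13 ± 0.223 CPM (log2 change -7.88 ± 0.3). Carbon fixation and glycolysis did not pass as lists. In the former 10 rose, 14 fell and 8 did not pass (10 and 14 adjusted over the list alone, camera adjusted p = 0.643). In the latter 32 rose, 34 fell and 29 did not pass (32 and 34 adjusted over the list alone, camera adjusted p = 0.751). The carbon fixation median was 0.09 relative to all genes beside a mean of -1.2. Glycolysis had a median and mean below 0 and a test statistic above 0. For nitrogen uptake and assimilation 28 rose, 17 fell and 9 did not pass (28 and 17 adjusted over the list alone, or 21 higher and 21 lower with library size alone). For the nitrogen list the median was 0.61 relative to all genes (camera adjusted p = 0.043, or adjusted p = 0.444 with an estimated correlation). Ferredoxin-nitrite reductase (TR36731:c0_g2), which turns nitrite into ammonium, rose from 11.9 ± 1.88 to 809 ± 169 CPM (log2 change 6.09 ± 0.19). NADH glutamate synthase (TR48898:c0_g1) fell from 32.2 ± 3.05 to 3.1 ± 1.17 CPM (log2 change -3.34 ± 0.27). In fatty acid synthesis and desaturation 35 of 73 members rose, 19 fell and 19 did not pass (35 and 19 adjusted over the list alone, or 24 higher and 32 lower with library size alone). For the fatty acid list the median was 0.73 relative to all genes (camera adjusted p = 0.0317, or adjusted p = 0.52 with an estimated correlation). Stearoyl-CoA 9-desaturase (TR23856:c13_g1) rose from 9.03 ± 1.43 to 456 ± 57.5 CPM (log2 change 5.66 ± 0.2). Among antioxidant enzymes 49 of 109 members rose, 25 fell and 35 did not pass (49 and 25 adjusted over the list alone, or 29 higher and 41 lower with library size alone). For the antioxidant enzymes the median was 0.59 relative to all genes (camera adjusted p = 0.043, or adjusted p = 0.334 with an estimated correlation), beside a mean of -0.04. Glutaredoxin-1 (TR36925:c1_g1) rose from 1.58 ± 0.285 to 154 ± 45.6 CPM (log2 change 6.6 ± 0.26). Glutaredoxin-C8 (TR46925:c0_g1) fell from 101 ± 20.5 to 0.414 ± 0.138 CPM (log2 change -7.92 ± 0.29). The largest edgeR adjusted p of these named genes was 4.79e-09.

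**Figure D2:**
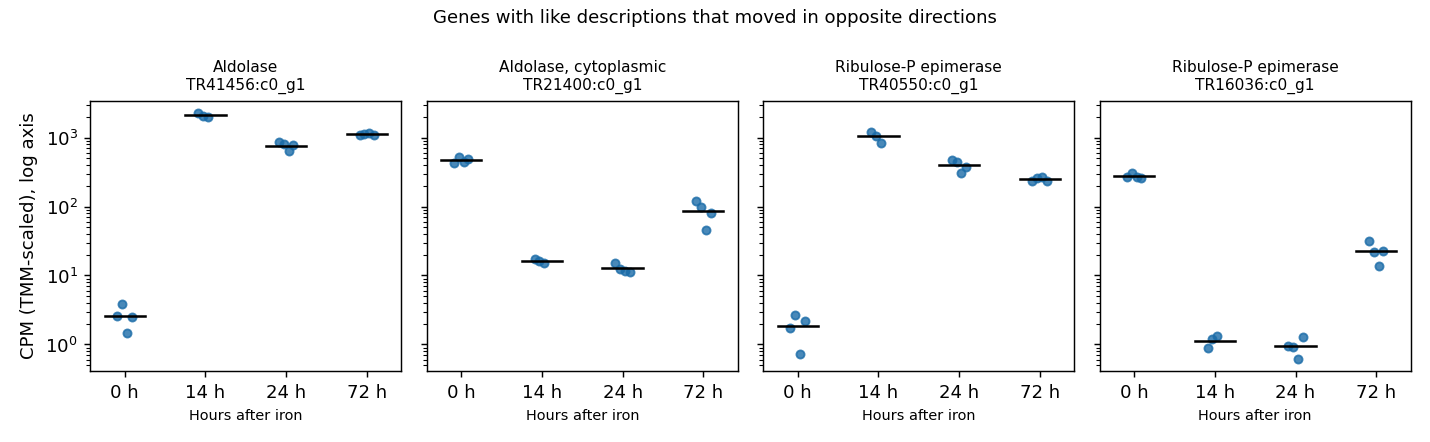
TMM-scaled CPM on a log axis against hours after iron for 2 genes described as fructose-bisphosphate aldolase and 2 described as ribulose-phosphate 3-epimerase, with 1 point per library and a line at the group mean. The aldolase TR41456:c0_g1 goes from a mean of 2.59 at 0 h to 2100 at 14 h, and the cytoplasmic isozyme TR21400:c0_g1 from 472 to 16.2.

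The lists for ribosomes and respiration lay above other genes at 14 h by the preset camera test, and those for DNA replication and flagella below them. Of the cytosolic ribosomal proteins 82 rose, 2 fell and 83 did not pass (80 and 2 adjusted over the list alone). For the ribosomal proteins the median was 1.69 relative to all genes (camera adjusted p = 4.42e-11, or adjusted p = 0.52 with an estimated correlation). Without replicate 3 of 14 h that median was 0.95. Ribosomal protein L34 of the 60S subunit (TR30683:c2_g1) rose from 220 ± 20.6 to 1260 ± 308 CPM (log2 change 2.51 ± 0.14). For ribosome biogenesis and RNA polymerase I 41 rose, 12 fell and 12 did not pass (41 and 13 adjusted over the list alone). For ribosome biogenesis the median was 1.63 relative to all genes (camera adjusted p = 0.000123, or adjusted p = 0.364 with an estimated correlation). Ribosome production factor 1 (TR48256:c0_g1), needed for the large subunit, rose from 23.2 ± 3.39 to 177 ± 40.4 CPM (log2 change 2.93 ± 0.18). In the mitochondrial respiratory chain 33 of 65 members rose, 12 fell and 20 did not pass (34 and 12 adjusted over the list alone). For the respiratory chain the median was 1.39 relative to all genes (camera adjusted p = 0.000528, or adjusted p = 0.444 with an estimated correlation). Subunit 6 of the cytochrome b-c1 complex (TR14864:c1_g1) rose from 4.29 ± 1.25 to 158 ± 39.6 CPM (log2 change 5.2 ± 0.22). The cytochrome b560 subunit of succinate dehydrogenase (TR21449:c0_g1) fell from 82.2 ± 5.03 to 1.69 ± 0.816 CPM (log2 change -5.55 ± 0.23). On the list for DNA replication and cell cycle 35 of 139 members rose, 66 fell and 38 did not pass (35 and 67 adjusted over the list alone). For the replication and cell cycle list the median was -0.57 relative to all genes (camera adjusted p = 0.0183, or adjusted p = 0.334 with an estimated correlation). The 70 kDa subunit of replication protein A (TR16475:c0_g1), which binds single-stranded DNA, fell from 366 ± 59.9 to 1.06 ± 0.472 CPM (log2 change -8.37 ± 0.24). Cyclin-B2-3 (TR35250:c0_g1), of a family that acts at the entry into mitosis, rose from 3.78 ± 0.941 to 190 ± 56 CPM (log2 change 5.64 ± 0.24). Flagellum and axoneme genes had 25 higher, 99 lower and 41 that did not pass (25 and 101 adjusted over the list alone). For the flagellum list the median was -1.24 relative to all genes (camera adjusted p = 1.71e-05, or adjusted p = 0.334 with an estimated correlation). The alpha chain of flagellar outer arm dynein (TR53067:c0_g1), a motor of the axoneme, fell from 18.6 ± 1.69 to 0.593 ± 0.588 CPM (log2 change -4.83 ± 0.4). Flagellar radial spoke protein 3 (TR16851:c0_g1) rose from 71 ± 8.87 to 186 ± 18.2 CPM (log2 change 1.39 ± 0.16). No gene named in this group had an edgeR adjusted p above 4.16e-07.

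Several genes were close to silent on 1 side of the comparison. Mitochondrial pyruvate carrier 4 (TR5045:c0_g1) had no count at 0 h and 49.3 ± 5.96 CPM at 14 h, at least 693-fold higher against a floor of 3 counts over the group. Regulatory protein PHO2 (TR41607:c0_g1) rose from 0.165 ± 0.165 to 225 ± 44.4 CPM (log2 change 10.29 ± 0.34). Protein Mpv17 (TR50699:c0_g1), of an inner mitochondrial membrane family, had 2 counts at 0 h and 77.2 ± 17.5 CPM at 14 h, a ratio of 1590 with a counting interval of 439 to 13100. A blue-light photoreceptor (TR14349:c1_g1) had 101 ± 12.1 CPM at 0 h and no count at 14 h, at least 670-fold lower against the same floor. So did a polyamine aminopropyl transferase (TR19270:c1_g1; 52.2 ± 9.49 CPM, at least 348-fold lower), ATP-dependent phosphoenolpyruvate carboxykinase (TR34111:c0_g1; 48.9 ± 23.3 CPM, at least 323-fold lower) and 4-hydroxy-3-methylbut-2-enyl diphosphate reductase (TR53636:c1_g1; 28.4 ± 2.59 CPM, at least 189-fold lower), the last an iron-sulfur enzyme of isoprenoid synthesis. Light receptors and clock genes went both ways, as 8 rose, 6 fell and 8 did not pass (8 and 6 adjusted over the list alone, or 6 higher and 8 lower with library size alone, camera adjusted p = 0.573). Phototropin-1 (TR22586:c0_g1), a blue-light receptor kinase, had 35.5 ± 6.22 CPM at 0 h and 2 counts at 14 h (a ratio of 353 with a counting interval of 97.5 to 2920), while phototropin-2 (TR3302:c0_g1) rose from 0.836 ± 0.106 to 24 ± 1.63 CPM (log2 change 4.83 ± 0.25). A gene described as vitellogenin (TR10703:c0_g1), an animal yolk protein, rose from 0.144 ± 0.122 to 249 ± 328 CPM (log2 change 10.63 ± 3.46). Its edgeR adjusted p was 0.0189, and 0.0638 without replicate 3 of 14 h (log2 change 8.65), within 1.69e-05 to 0.0638 over its alternatives. All 25 such genes together held 208, 1160 and 3.83 CPM in replicates 1, 3 and 4 of 14 h and at most 1.44 CPM in a 0 h library. Lists of bacterial markers and of mobile elements and viral genes did not pass. Of the bacterial markers 10 rose, 3 fell and 7 did not pass (11 and 3 adjusted over the list alone, or 5 higher and 7 lower with library size alone, camera adjusted p = 0.203). Apart from the vitellogenin gene, the largest edgeR adjusted p among the genes with a log2 change in this group was 7.27e-12.

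Across all genes tested, edgeR called 35177 of 56541 at 14 h (adjusted p under 0.05), 16549 higher and 18628 lower, and 35371 with culture number as a block. At least 4-fold changes were more often downward, with 5438 higher and 10313 lower, and so were changes of at least 16-fold, with 785 and 3529. With library size alone in place of TMM scaling the split was 9365 higher and 27203 lower, and the median log2 change over all genes went from -0.11 to -0.79. Camera called 11 of the 28 lists tested, and the 17 others had adjusted p from 0.0882 to 0.871; with an estimated correlation between genes none of the 11 was called (adjusted p from 0.334 to 0.52 with an estimated correlation). The antioxidant call was lost without replicate 2 or 4 of 0 h or replicate 1 of 14 h (camera adjusted p = 0.0671, 0.0548 and 0.0967), with library size alone (0.0559) and with culture number as a block (0.0569), within 0.0164 to 0.334 over its alternatives. Other lost calls were fatty acid synthesis without replicate 4 of 0 h or 1 of 14 h (camera adjusted p = 0.0548 and 0.0801, within 0.0109 to 0.52), nitrogen assimilation without replicate 4 of 0 h or of 14 h (0.0548 and 0.0765, within 0.00924 to 0.443) and ribosome biogenesis without a filter on low counts (0.0962, within 6.54e-06 to 0.364; median 0.21 in place of 1.63).

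**Figure D3:**
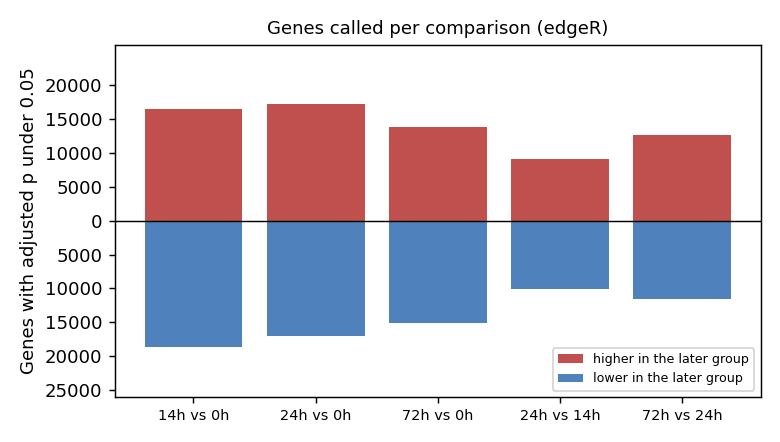
Number of genes with an edgeR adjusted p under 0.05 in each of the 5 comparisons, with bars above 0 for genes higher and bars below 0 for genes lower in the later group. The bars stand at 16549 higher and 18628 lower for 14 h against 0 h, and at 13812 and 15059 for 72 h against 0 h.

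The comparison of 24 h with 0 h was made at the same clock time, a full day after iron. Most iron-containing carriers of the plastid were above their level before iron, and flavodoxin was below it. Ferredoxin-2 (TR49266:c0_g4) rose from 7.82 ± 1.61 to 1960 ± 91.8 CPM (log2 change 7.97 ± 0.2). The cytochrome b6-f iron-sulfur subunit (TR36823:c0_g1) rose from 245 ± 78.7 to 1980 ± 361 CPM (log2 change 3.01 ± 0.2). Flavodoxin (TR4324:c0_g1) fell from 1220 ± 90.6 to 27.2 ± 3.1 CPM (log2 change -5.49 ± 0.17). Plastocyanin (TR49637:c0_g1) differed little, with 1720 ± 160 CPM at 0 h and 1900 ± 257 CPM at 24 h (log2 change 0.15 ± 0.12, edgeR adjusted p = 0.281). Its sign turned with library size alone (-0.4, edgeR adjusted p = 0.000676, within 0.000676 to 0.709 over its alternatives). Of the iron-containing plastid carriers 13 rose, 1 fell and 4 did not pass (13 and 1 adjusted over the list alone). For the plastid carriers the median was 3.16 relative to all genes (camera adjusted p = 7.21e-07, or adjusted p = 0.0875 with an estimated correlation). Assembly of iron-sulfur clusters rose, where 13 rose, 1 fell and 7 did not pass (13 and 1 adjusted over the list alone). For cluster assembly the median was 1.05 relative to all genes (camera adjusted p = 0.000619, or adjusted p = 0.0487 with an estimated correlation), the only list at this time that passed in both ways. IscA (TR22395:c7_g1) rose from 3.42 ± 0.834 to 22.4 ± 2.24 CPM (log2 change 2.71 ± 0.21). Vacuolar iron transporter 1.1 (TR36365:c0_g1) rose from 22.9 ± 4.06 to 294 ± 35.9 CPM (log2 change 3.68 ± 0.15). Multicopper oxidase (TR3087:c10_g1) fell from 48 ± 9.37 to 1.64 ± 0.418 CPM (log2 change -4.87 ± 0.33), and chloroplast heme oxygenase 1 (TR50927:c0_g1), which opens the heme ring, rose from 101 ± 3.42 to 218 ± 44.9 CPM (log2 change 1.11 ± 0.13). Iron uptake and iron storage did not pass as lists. For uptake 8 rose, 3 fell and 7 did not pass (8 and 3 adjusted over the list alone, or 3 higher and 5 lower with library size alone, camera adjusted p = 0.407). Of the members left without vacuolar transporters and kinases, 2 of 8 rose and 3 fell (median -0.73 relative to all genes, camera adjusted p = 0.38). For storage and heme breakdown 8 rose, 2 fell and 3 did not pass (8 and 2 adjusted over the list alone, or 4 higher and 3 lower with library size alone, camera adjusted p = 0.273). Called genes named for iron at 24 h had an edgeR adjusted p of at most 1.15e-06.

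Photosystem genes had the smallest camera p of the lists at 24 h. Of the photosystem subunits 24 rose, 0 fell and 4 did not pass (25 and 0 adjusted over the list alone). For the photosystem subunits the median was 2.6 relative to all genes (camera adjusted p = 1.5e-11, or adjusted p = 0.14 with an estimated correlation). Subunit IV of photosystem I (TR15286:c0_g1), which takes part in ferredoxin docking, rose from 98.7 ± 10.6 to 1130 ± 314 CPM (log2 change 3.52 ± 0.2). In the antenna 47 of 79 members rose, 21 fell and 11 did not pass (47 and 21 adjusted over the list alone). For the antenna the median was 1.76 relative to all genes (camera adjusted p = 1.35e-05, or adjusted p = 0.5 with an estimated correlation). TR16889:c0_g1, a fucoxanthin-chlorophyll protein A, rose from 92.1 ± 16.7 to 734 ± 42 CPM (log2 change 2.99 ± 0.13). TR16388:c2_g1 fell from 137 ± 6.28 to 0.364 ± 0.259 CPM (log2 change -8.49 ± 0.33). Chlorophyll and heme biosynthesis, not called at 14 h, had 22 higher, 1 lower and 8 that did not pass (23 and 1 adjusted over the list alone). For the chlorophyll list the median was 1.03 relative to all genes (camera adjusted p = 8.9e-06, or adjusted p = 0.156 with an estimated correlation). Magnesium-protoporphyrin O-methyltransferase (TR38038:c12_g1), of the chlorophyll branch, rose from 83.2 ± 3.29 to 289 ± 15.5 CPM (log2 change 1.8 ± 0.13). For photoprotection and carotenoid synthesis 19 rose, 3 fell and 12 did not pass (19 and 3 adjusted over the list alone, or 9 higher and 7 lower with library size alone). For the photoprotection list the median was 0.59 relative to all genes (camera adjusted p = 0.00548, or adjusted p = 0.134 with an estimated correlation). Violaxanthin de-epoxidase (TR6463:c0_g1) rose from 21.3 ± 3.42 to 68.5 ± 4.87 CPM (log2 change 1.69 ± 0.13). PROTON GRADIENT REGULATION 5 (TR21521:c0_g1), of cyclic electron flow, rose from 0.449 ± 0.149 to 103 ± 9.21 CPM (log2 change 7.79 ± 0.21). Among these photosynthesis genes the largest edgeR adjusted p was 4.54e-09.

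The lists for cytosolic ribosomes and respiration lay above other genes at 24 h by the preset camera test, and flagellar genes below them. In glycolysis 48 of 95 members rose, 18 fell and 29 did not pass (48 and 19 adjusted over the list alone, or 24 higher and 28 lower with library size alone). For glycolysis the median was 0.51 relative to all genes (camera adjusted p = 0.00695, or adjusted p = 0.0875 with an estimated correlation). Its pattern also took in 22 methyltransferases and mutase-like proteins, and without these, a step chosen once the members were seen, 34 of 73 rose and 15 fell (median 0.31 relative to all genes, camera adjusted p = 0.0356). Aldolase TR41456:c0_g1 rose from 2.59 ± 0.982 to 767 ± 87.5 CPM (log2 change 8.21 ± 0.22). The cytoplasmic isozyme TR21400:c0_g1 fell from 472 ± 44 to 12.7 ± 1.75 CPM (log2 change -5.22 ± 0.25). Ribulose-phosphate 3-epimerase TR40550:c0_g1 rose from 1.85 ± 0.841 to 398 ± 71 CPM (log2 change 7.75 ± 0.27), and chloroplast fructose-1,6-bisphosphatase (TR48800:c18_g1) fell from 110 ± 4.52 to 0.224 ± 0.156 CPM (log2 change -8.88 ± 0.31). Carbon fixation did not pass as a list, as 10 rose, 11 fell and 11 did not pass (10 and 12 adjusted over the list alone, camera adjusted p = 0.818). Cytosolic ribosomal proteins had 96 higher, 4 lower and 67 that did not pass (96 and 4 adjusted over the list alone). For the ribosomal proteins the median was 1.29 relative to all genes (camera adjusted p = 1.01e-10, or adjusted p = 0.553 with an estimated correlation). L34 (TR30683:c2_g1) rose from 220 ± 20.6 to 965 ± 37.7 CPM (log2 change 2.13 ± 0.14). The respiratory chain had 38 higher, 13 lower and 14 that did not pass (41 and 13 adjusted over the list alone). For the respiratory chain the median was 1.12 relative to all genes (camera adjusted p = 6.24e-05, or adjusted p = 0.41 with an estimated correlation). For fatty acid synthesis 38 rose, 19 fell and 16 did not pass (38 and 19 adjusted over the list alone, or 26 higher and 25 lower with library size alone). For the fatty acid list the median was 0.56 relative to all genes (camera adjusted p = 0.0315, or adjusted p = 0.553 with an estimated correlation), beside a mean of 0. Antioxidant enzymes had 52 higher, 22 lower and 35 that did not pass (52 and 23 adjusted over the list alone, or 38 higher and 31 lower with library size alone). For the antioxidant enzymes the median was 0.43 relative to all genes (camera adjusted p = 0.00695, or adjusted p = 0.14 with an estimated correlation). Glutaredoxin TR46105:c8_g1 rose from 36.7 ± 5.03 to 145 ± 14.2 CPM (log2 change 1.98 ± 0.16). Glutathione peroxidase TR45938:c10_g1 fell from 134 ± 21 to 0.332 ± 0.194 CPM (log2 change -8.61 ± 0.32). Flagellum and axoneme genes had 10 higher, 109 lower and 46 that did not pass (11 and 112 adjusted over the list alone). For the flagellum list the median was -1.56 relative to all genes (camera adjusted p = 2.24e-11, or adjusted p = 0.0875 with an estimated correlation). The gamma chain of outer arm dynein (TR2911:c7_g1) fell from 107 ± 9.85 to 1.24 ± 0.744 CPM (log2 change -6.43 ± 0.37). Non-symbiotic hemoglobin 1 (TR41093:c1_g1), a heme protein, rose from 0.168 ± 0.0515 to 49.6 ± 6.67 CPM (log2 change 8.1 ± 0.31). Hsp70-Hsp90 organizing protein 1 (TR14963:c0_g1), a co-chaperone, rose from 0.181 ± 0.361 to 47.7 ± 12.2 CPM (log2 change 7.87 ± 0.86). The largest edgeR adjusted p of these genes was 5.62e-06.

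At 24 h edgeR called 34291 genes, 17203 higher and 17088 lower, or 8871 and 23886 with library size alone, and 34527 with culture number as a block. Changes of at least 4-fold were 2576 upward and 8604 downward. Camera called 12 of 28 lists, and the 16 others had adjusted p from 0.0681 to 0.985. Among the latter was nitrogen assimilation, where 24 rose, 14 fell and 16 did not pass (24 and 15 adjusted over the list alone, or 17 higher and 22 lower with library size alone, camera adjusted p = 0.271). So were the bacterial markers, where 10 rose, 3 fell and 7 did not pass (12 and 3 adjusted over the list alone, or 3 higher and 4 lower with library size alone, camera adjusted p = 0.0681). The fatty acid call was lost without replicate 4 of 0 h or replicate 1 of 24 h (camera adjusted p = 0.0677 and 0.0685, within 0.0111 to 0.553 over its alternatives). Genes described as vitellogenin held 2710 CPM in replicate 1 of 24 h and 0.819, 32.3 and 0.241 CPM in replicates 2 to 4.

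After 3 days flavodoxin and ferredoxin-2 lay between their levels at 0 h and 24 h, while plastocyanin lay above its level at 0 h. Flavodoxin (TR4324:c0_g1), at 275 ± 58.4 CPM, was still below the 1220 ± 90.6 CPM of 0 h (log2 change -2.15 ± 0.14). Ferredoxin-2 (TR49266:c0_g4) rose from 7.82 ± 1.61 to 1380 ± 109 CPM (log2 change 7.46 ± 0.19). Plastocyanin (TR49637:c0_g1) rose from 1720 ± 160 to 2310 ± 153 CPM (log2 change 0.43 ± 0.12), a call that ended with library size alone (0.08, edgeR adjusted p = 0.447, the highest of its alternatives from 0.00207 to 0.447). Of the iron-containing plastid carriers 13 rose, 0 fell and 5 did not pass (14 and 0 adjusted over the list alone). For the plastid carriers the median was 2.03 relative to all genes (camera adjusted p = 3.94e-07, or adjusted p = 0.0622 with an estimated correlation). Assembly of iron-sulfur clusters had 15 higher, 1 lower and 5 that did not pass (15 and 1 adjusted over the list alone). For cluster assembly the median was 0.78 relative to all genes (camera adjusted p = 0.000544, or adjusted p = 0.02 with an estimated correlation). NBP35 of the cytosolic pathway (TR40637:c7_g1) rose from 11 ± 1.96 to 37 ± 1.66 CPM (log2 change 1.75 ± 0.15). Vacuolar iron transporter 1 (TR38962:c8_g1) rose from 2.37 ± 0.314 to 18.9 ± 5.45 CPM (log2 change 3 ± 0.22). Mitoferrin-1 (TR10137:c0_g1) fell from 68.7 ± 9.67 to 1.43 ± 0.668 CPM (log2 change -5.62 ± 0.29). A vanadium-dependent bromoperoxidase (TR12707:c12_g1), of a family that halogenates organic compounds with peroxide, rose from 1.84 ± 0.655 to 356 ± 40 CPM (log2 change 7.59 ± 0.34). Iron uptake and iron storage again did not pass as lists. For uptake 9 rose, 4 fell and 5 did not pass (9 and 4 adjusted over the list alone, or 7 higher and 5 lower with library size alone, camera adjusted p = 0.195). Without vacuolar transporters and kinases 2 of 8 rose and 2 fell (median -0.01 relative to all genes, camera adjusted p = 0.704). For storage and heme breakdown 8 rose, 4 fell and 1 did not pass (8 and 4 adjusted over the list alone, or 4 higher and 4 lower with library size alone, camera adjusted p = 0.371), with a median above 0 and a mean of -0.36. The largest edgeR adjusted p among these genes was 0.00503.

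Most genes of light harvesting, photosystems and pigments were higher at 72 h than before iron. The antenna had 51 higher, 9 lower and 19 that did not pass (51 and 10 adjusted over the list alone). For the antenna the median was 1.56 relative to all genes (camera adjusted p = 4.12e-11, or adjusted p = 0.241 with an estimated correlation). TR40626:c2_g1 rose from 15.8 ± 2.89 to 381 ± 27.7 CPM (log2 change 4.59 ± 0.16). TR32592:c0_g1 fell from 68.9 ± 21.1 to 0.48 ± 0.414 CPM (log2 change -7.25 ± 0.56). Photosystem subunits had 24 higher, 0 lower and 4 that did not pass (24 and 0 adjusted over the list alone). For the photosystem subunits the median was 1.83 relative to all genes (camera adjusted p = 6.14e-10, or adjusted p = 0.159 with an estimated correlation). For chlorophyll and heme biosynthesis 23 rose, 1 fell and 7 did not pass (24 and 1 adjusted over the list alone). For the chlorophyll list the median was 1 relative to all genes (camera adjusted p = 3.18e-07, or adjusted p = 0.117 with an estimated correlation). Uroporphyrinogen decarboxylase (TR33169:c0_g1) rose from 31.4 ± 2.97 to 105 ± 9.53 CPM (log2 change 1.74 ± 0.15). Photoprotection and carotenoid synthesis had 24 higher, 3 lower and 7 that did not pass (24 and 3 adjusted over the list alone). For the photoprotection list the median was 0.94 relative to all genes (camera adjusted p = 4.96e-06, or adjusted p = 0.02 with an estimated correlation). Zeaxanthin epoxidase (TR21334:c0_g1) rose from 2.92 ± 1.21 to 17.8 ± 1.4 CPM (log2 change 2.6 ± 0.23). Zeta-carotene desaturase (TR38618:c1_g1) fell from 64.2 ± 9.7 to 24.6 ± 5.93 CPM (log2 change -1.39 ± 0.18). Carbon fixation went both ways, with 11 higher, 12 lower and 9 that did not pass (11 and 12 adjusted over the list alone, or 9 higher and 12 lower with library size alone, camera adjusted p = 0.789), and had a median of 0.17 relative to all genes beside a mean of -0.07. In glycolysis 50 of 95 members rose, 18 fell and 27 did not pass (52 and 19 adjusted over the list alone, or 31 higher and 24 lower with library size alone). For glycolysis the median was 0.6 relative to all genes (camera adjusted p = 0.000388, or adjusted p = 0.02 with an estimated correlation). Without the 22 members set aside before, 39 of 73 rose and 17 fell (median 0.6 relative to all genes, camera adjusted p = 0.00323). Aldolase TR41456:c0_g1 rose from 2.59 ± 0.982 to 1120 ± 32.6 CPM (log2 change 8.76 ± 0.22). Antioxidant enzymes had 58 higher, 27 lower and 24 that did not pass (58 and 28 adjusted over the list alone). For the antioxidant enzymes the median was 0.71 relative to all genes (camera adjusted p = 0.00184, or adjusted p = 0.105 with an estimated correlation). A putative peroxiredoxin (TR17350:c0_g1), a thiol peroxidase, rose from 13.3 ± 2.44 to 94.2 ± 3.96 CPM (log2 change 2.82 ± 0.22). No gene of this group had an edgeR adjusted p above 3.36e-06.

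Most genes of ribosome production were lower at 72 h. On the list for ribosome biogenesis and RNA polymerase I 2 of 65 members rose, 43 fell and 20 did not pass (2 and 45 adjusted over the list alone). For ribosome biogenesis the median was -1.08 relative to all genes (camera adjusted p = 3.94e-07, or adjusted p = 0.19 with an estimated correlation). The homolog of U3 small nucleolar RNA-associated protein 21 (TR18619:c1_g1), of the small-subunit processome, fell from 21.5 ± 4.26 to 5.9 ± 0.629 CPM (log2 change -1.87 ± 0.2). Cytosolic ribosomal proteins were divided, as 76 rose, 72 fell and 19 did not pass (76 and 73 adjusted over the list alone, camera adjusted p = 0.223). L34 (TR30683:c2_g1) rose from 220 ± 20.6 to 621 ± 45.9 CPM (log2 change 1.49 ± 0.13). L10 (TR39056:c0_g2) fell from 51.8 ± 10.7 to 16.1 ± 2.8 CPM (log2 change -1.68 ± 0.2). The respiratory chain had 33 higher, 21 lower and 11 that did not pass (35 and 21 adjusted over the list alone, or 27 higher and 22 lower with library size alone). For the respiratory chain the median was 1 relative to all genes (camera adjusted p = 0.0295, or adjusted p = 0.546 with an estimated correlation). Cytochrome b-c1 subunit 6 (TR14864:c1_g1) rose from 4.29 ± 1.25 to 79 ± 5.57 CPM (log2 change 4.2 ± 0.21). The succinate dehydrogenase flavoprotein (TR4397:c0_g1) fell from 25.3 ± 4.95 to 5.41 ± 0.797 CPM (log2 change -2.21 ± 0.2). Flagellum and axoneme genes had 2 higher, 127 lower and 36 that did not pass (2 and 131 adjusted over the list alone). For the flagellum list the median was -1.62 relative to all genes (camera adjusted p = 8.32e-17, or adjusted p = 0.02 with an estimated correlation). The gamma chain of outer arm dynein (TR2911:c7_g1) fell from 107 ± 9.85 to 6.84 ± 2.22 CPM (log2 change -3.96 ± 0.29). Cell cycle genes did not pass as a list, with 57 higher, 29 lower and 53 that did not pass (61 and 31 adjusted over the list alone, or 32 higher and 42 lower with library size alone, camera adjusted p = 0.0946). Replication factor C subunit 3 (TR33748:c0_g1), a clamp loader, rose from 182 ± 8.18 to 416 ± 18.4 CPM (log2 change 1.19 ± 0.11). Condensin complex subunit 2 (TR34940:c0_g1) fell from 18.5 ± 4.4 to 5.08 ± 1.16 CPM (log2 change -1.87 ± 0.22). Cytochrome c (TR1205:c0_g1) fell from 268 ± 32.3 to 4.09 ± 1.38 CPM (log2 change -6.01 ± 0.22). The largest edgeR adjusted p among these genes was 2.1e-06.

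At 72 h edgeR called 28871 genes, 13812 higher and 15059 lower, or 8216 and 20138 with library size alone, and 29484 with culture number as a block. At least 4-fold changes numbered 1610 upward and 4758 downward. Camera called 11 of 28 lists, of which flagellum, glycolysis, iron-sulfur cluster assembly and photoprotection also passed with an estimated correlation, and the 17 others had adjusted p from 0.0614 to 0.86. The respiratory call was lost without replicate 1 or 3 of 72 h (camera adjusted p = 0.0501 and 0.0533, within 0.00504 to 0.546 over its alternatives). Vitellogenin genes held 0.694, 15, 0.312 and 2.19 CPM in the 4 libraries of 72 h.

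**Figure D4:**
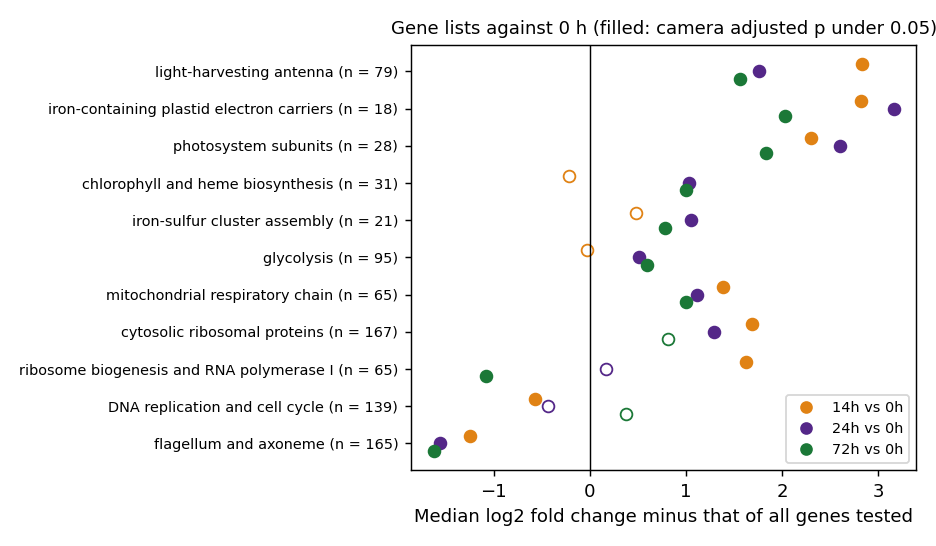
Median log2 fold change of 11 gene lists minus that of all genes tested, with 1 point per list for 14 h, 24 h and 72 h against 0 h, filled where the camera adjusted p was under 0.05. Antenna genes lie at 2.83, 1.76 and 1.56 and flagellum and axoneme genes at -1.24, -1.56 and -1.62.

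Between 14 h and 24 h several genes that had fallen at 14 h rose again. Protochlorophyllide reductase A (TR7137:c7_g1) rose from 1.59 ± 1.15 to 327 ± 26.9 CPM (log2 change 7.6 ± 0.29). Plastocyanin (TR49637:c0_g1) rose from 107 ± 6.76 to 1900 ± 257 CPM (log2 change 4.15 ± 0.15). Replication protein A (TR16475:c0_g1) rose from 1.06 ± 0.472 to 206 ± 6.48 CPM (log2 change 7.54 ± 0.24). The blue-light photoreceptor TR14349:c1_g1, without a count at 14 h, had 21.8 ± 5.96 CPM at 24 h (at least 143-fold higher). In the other direction, the antenna gene TR53578:c2_g1 fell from 537 ± 189 to 8.36 ± 0.971 CPM (log2 change -6 ± 0.23). Zeaxanthin epoxidase (TR21334:c0_g1) fell from 234 ± 32.3 to 6.22 ± 1.93 CPM (log2 change -5.23 ± 0.25). Flavodoxin (TR4324:c0_g1) stayed low, with 21.4 ± 0.488 CPM at 14 h and 27.2 ± 3.1 CPM at 24 h (log2 change 0.35 ± 0.16, edgeR adjusted p = 0.111), and by library size alone it was called (0.5, edgeR adjusted p = 0.0381, within 0.0381 to 0.228 over its alternatives). Ferredoxin-2 (TR49266:c0_g4) stayed high, with 2160 ± 462 CPM at 14 h and 1960 ± 91.8 CPM at 24 h (log2 change -0.14 ± 0.15, edgeR adjusted p = 0.52). Its value turned to 0.04 with library size alone. Chlorophyll and heme biosynthesis rose, where 24 rose, 0 fell and 7 did not pass (24 and 0 adjusted over the list alone). For the chlorophyll list the median was 1.1 relative to all genes (camera adjusted p = 1.03e-11, or adjusted p = 0.129 with an estimated correlation). Photoprotection and carotenoid synthesis had 18 higher, 9 lower and 7 that did not pass (19 and 9 adjusted over the list alone). For the photoprotection list the median was 0.85 relative to all genes (camera adjusted p = 0.00234, or adjusted p = 0.129 with an estimated correlation). DNA replication and cell cycle had 48 higher, 19 lower and 72 that did not pass (49 and 22 adjusted over the list alone). For the replication and cell cycle list the median was 0.21 relative to all genes (camera adjusted p = 0.00234, or adjusted p = 0.129 with an estimated correlation). Photosystem subunits had 13 higher, 2 lower and 13 that did not pass (13 and 2 adjusted over the list alone). For the photosystem subunits the median was 0.57 relative to all genes (camera adjusted p = 0.014, or adjusted p = 0.541 with an estimated correlation). The list for iron uptake had 7 higher, 0 lower and 11 that did not pass (8 and 0 adjusted over the list alone). For the iron uptake list the median was 0.74 relative to all genes (camera adjusted p = 0.0305, or adjusted p = 0.307 with an estimated correlation). This call was lost without the 10 vacuolar transporters and kinases, where 1 of 8 rose and 0 fell (median 0.52 relative to all genes, camera adjusted p = 0.537). Ribosome biogenesis and RNA polymerase I fell, where 0 rose, 45 fell and 20 did not pass (0 and 45 adjusted over the list alone). For ribosome biogenesis the median was -1.35 relative to all genes (camera adjusted p = 1.03e-11, or adjusted p = 0.129 with an estimated correlation). Nitrogen assimilation had 5 higher, 26 lower and 23 that did not pass (6 and 27 adjusted over the list alone). For the nitrogen list the median was -0.55 relative to all genes (camera adjusted p = 0.00756, or adjusted p = 0.348 with an estimated correlation). The antenna had 15 higher, 33 lower and 31 that did not pass (16 and 33 adjusted over the list alone, or 23 higher and 33 lower with library size alone). For the antenna the median was -0.21 relative to all genes (camera adjusted p = 0.000163, or adjusted p = 0.513 with an estimated correlation), beside a mean of -2.18. Without replicate 1 or 3 of 14 h or 1 or 3 of 24 h that median was -0.04, -0.1, -0.12 and -0.02. The photosystem median was 1.01 without replicate 1 of 14 h, and that of the flagellum list -0.26 without replicate 4. Flagellum and axoneme genes had 9 higher, 50 lower and 106 that did not pass (10 and 50 adjusted over the list alone). For the flagellum list the median was -0.45 relative to all genes (camera adjusted p = 0.0111, or adjusted p = 0.461 with an estimated correlation). Aminoacyl-tRNA synthetases had 8 higher, 25 lower and 35 that did not pass (8 and 27 adjusted over the list alone). For the synthetases the median was -0.44 relative to all genes (camera adjusted p = 0.00331, or adjusted p = 0.129 with an estimated correlation). The largest edgeR adjusted p among the called genes was 5.1e-12.

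This comparison, which spans a change in clock time, called 19228 genes in edgeR, 9143 higher and 10085 lower at 24 h, with 3311 and 2103 changed at least 4-fold. With library size alone the majority turned, to 10587 higher and 8041 lower, and with culture number as a block 19444 were called. Camera called 10 lists, none of them with an estimated correlation, and the 18 others had adjusted p from 0.0736 to 0.732. The photosystem call was lost without replicate 4 of 14 h (camera adjusted p = 0.103, within 0.000271 to 0.541 over its alternatives). The iron uptake call was also lost without replicate 3 of 14 h, replicate 1 of 24 h or a filter on low counts (camera adjusted p = 0.0827, 0.0672 and 0.106, within 0.0125 to 0.537, with medians of 0.46, 0.73 and 0.54).

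From 24 h to 72 h flavodoxin and ferredoxin-2 moved part of the way back to their levels at 0 h. Flavodoxin (TR4324:c0_g1) rose from 27.2 ± 3.1 to 275 ± 58.4 CPM (log2 change 3.34 ± 0.15). Ferredoxin-2 (TR49266:c0_g4) fell from 1960 ± 91.8 to 1380 ± 109 CPM (log2 change -0.51 ± 0.14). The cytochrome b6-f iron-sulfur subunit (TR36823:c0_g1) fell from 1980 ± 361 to 991 ± 43.3 CPM (log2 change -1 ± 0.18). Vacuolar iron transporter 1.1 (TR36365:c0_g1) fell from 294 ± 35.9 to 69.7 ± 0.723 CPM (log2 change -2.07 ± 0.14). The ferredoxin-2 call ended with library size alone (-0.31, edgeR adjusted p = 0.0642, within 0.00672 to 0.0642 over its alternatives). Antenna gene TR40626:c2_g1 rose from 33 ± 4.58 to 381 ± 27.7 CPM (log2 change 3.53 ± 0.16). Cytosolic ribosomal proteins fell, where 1 rose, 136 fell and 30 did not pass (1 and 155 adjusted over the list alone). For the ribosomal proteins the median was -1.18 relative to all genes (camera adjusted p = 1.79e-19, or adjusted p = 0.442 with an estimated correlation). L34 (TR30683:c2_g1) fell from 965 ± 37.7 to 621 ± 45.9 CPM (log2 change -0.64 ± 0.13). Photosystem subunits fell, with 0 higher, 18 lower and 10 that did not pass (0 and 18 adjusted over the list alone). For the photosystem subunits the median was -0.9 relative to all genes (camera adjusted p = 7.16e-06, or adjusted p = 0.432 with an estimated correlation). Ribosome biogenesis fell as well, with 4 higher, 36 lower and 25 that did not pass (5 and 37 adjusted over the list alone). For ribosome biogenesis the median was -1 relative to all genes (camera adjusted p = 2.14e-06, or adjusted p = 0.432 with an estimated correlation). The respiratory chain had 6 higher, 30 lower and 29 that did not pass (6 and 34 adjusted over the list alone). For the respiratory chain the median was -0.71 relative to all genes (camera adjusted p = 2.25e-05, or adjusted p = 0.432 with an estimated correlation). Iron-containing plastid carriers had 1 higher, 10 lower and 7 that did not pass (1 and 11 adjusted over the list alone). For the plastid carriers the median was -0.56 relative to all genes (camera adjusted p = 0.00756, or adjusted p = 0.432 with an estimated correlation). DNA replication and cell cycle genes had 61 higher, 24 lower and 54 that did not pass (61 and 26 adjusted over the list alone). For the replication and cell cycle list the median was 0.47 relative to all genes (camera adjusted p = 0.012, or adjusted p = 0.432 with an estimated correlation). Replication protein A (TR16475:c0_g1) rose from 206 ± 6.48 to 487 ± 35.2 CPM (log2 change 1.24 ± 0.14). Called genes named here had an edgeR adjusted p of at most 0.00812. In all, edgeR called 24306 genes, 12712 higher and 11594 lower at 72 h, or 15135 and 8270 with library size alone. At least 4-fold changes numbered 4373 and 1753, and 25032 genes were called with culture number as a block. Camera called 6 lists, none with an estimated correlation, and the 22 others had adjusted p from 0.0516 to 0.967. Without a filter on low counts the replication call was lost (camera adjusted p = 0.0756, within 0.00523 to 0.433 over its alternatives; median 0.26), and the ribosome biogenesis median was -0.01. The ribosomal protein median was -0.77 without replicate 1 of 24 h.

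Many genes were called in the same direction at more than 1 time after iron. At 14 h and 24 h edgeR called 24876 genes in the same direction, 11584 higher and 13292 lower, where independent calls would give 5035 and 5630, and 1305 in opposite directions. For 14 h and 72 h these were 15741 genes, 7035 and 8706 against 4043 and 4961, with 4168 opposite. For 24 h and 72 h they were 20015 genes, 9821 and 10194 against 4202 and 4551, with 1171 opposite. These comparisons share the 4 libraries of 0 h. With those libraries divided so that the 2 comparisons shared none, the counts averaged 20235 (20101 to 20385 over 6 divisions), 12030 (11898 to 12157) and 15099 (14876 to 15362). Unchanged groups simulated against the same 0 h libraries shared 0 genes in each of 20 draws. They were drawn around the mean of those libraries, so this cannot show what sharing them adds. At all 3 times 14557 genes were called in the same direction, 6456 higher and 8101 lower, among them ferredoxin-2 and aldolase TR41456:c0_g1 upward and flavodoxin and the outer arm dynein gamma chain TR2911:c7_g1 downward. Another 3366 genes were called at 14 h, called in the opposite direction from 14 h to 24 h, and not called against 0 h at 24 h or 72 h, 1559 of them higher and 1807 lower at 14 h. Protochlorophyllide reductase A, at 314 ± 13.1, 1.59 ± 1.15, 327 ± 26.9 and 308 ± 14.2 CPM from 0 h to 72 h, was among them, though library size alone called it lower at 24 h (-0.49, edgeR adjusted p = 0.0348).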

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

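The tests of the vitellogenin genes, of clock time and of changes of at least 4-fold at 14 h were chosen only after the result was seen. Other divisions of the libraries did not give such counts of genes. In fits of the 2 groups alone edgeR called 33077 genes for 14 h against 0 h, 29913 for 24 h, 29890 for 72 h, 13713 for 24 h against 14 h and 20037 for 72 h against 24 h. For each, 1 of the 35 splits of the libraries, the real one, gave as many. The highest other split called 0, 0, 1, 0 and 0 genes. This argues against chance only if libraries are taken as interchangeable, which the pairing by culture number does not grant. The splits that part as many numbered pairs as the real one were 8, too few for a share under 0.05, and the highest other among them called 0, 0, 1, 0 and 0 genes. The other splits keep some pairs within a group.

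Genes described as vitellogenin stood far apart in single libraries, with 2710 CPM in replicate 1 of 24 h (others 0.241 to 32.3) and 15 CPM in replicate 2 of 72 h (others 0.312 to 2.19). So did a set of 20 other genes described as arthropod proteins, with 30.3 CPM in replicate 2 of 0 h (others 0.231 to 1.7) and 123 CPM in replicate 4 of 72 h (others 0 to 0.167), and they had 133 and 50.3 CPM in replicates 1 and 3 of 24 h. In 0 of the 3 groups after iron did every library lie 10-fold above the highest library of 0 h. This argues against a response to iron shared by the cultures. Of 12 other markers 1 held at least 70% of its counts in 1 library (0.299% of genes with 50 counts did). This cannot decide on animal RNA in single libraries only, as the main vitellogenin genes fell short (67.2% and 66%) and markers shared assembly clusters. RNA of an arthropod in several libraries in differing amounts, an explanation set up after that test, cannot be told apart. Vitellogenin and the other markers had a rank correlation of 0.56 over the 15 libraries, between the bounds set. Which animal it might be was not examined, and the 1.2 µm filter would hold back animals too.

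At 14 h, 3366 genes were called and were back by 24 h. Scaling cannot be told apart for all of them, since 79.4% kept both calls with library size alone and 95.1% under RLE, and the lower share was short of the bound set for excluding it. For the 1451 genes that changed at least 4-fold (532 higher, 919 lower) it is argued against as the cause. RLE and library size alone moved the median log2 change of all genes by at most 0.68 from that with TMM, where 4-fold is 2. The clock time of the 14 h sample cannot be told apart from a brief response to iron for any of the 3366 genes, because no culture without iron was sampled at that time of the light and dark cycle. Both may contribute, and the response to iron was not tested apart.

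Fewer genes had counts after iron than before. Library depth is argued against, since at equal counts per library the highest number after iron, 84798, was below the lowest at 0 h, 91534. A few genes taking most of the counts are argued against as well, since with the 500 most abundant genes of each library set aside the highest after iron was 83592 and the lowest at 0 h 88060. RNA of other organisms in the 0 h cultures and a broader expression under iron limitation were not tested.

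Among the genes named here by the rule, 13 of 267 groups of 4 libraries held a library far from the rest, where chance flags about 1 in 20 groups (13.4 expected). Of 21 groups of library measures 4 also held one (1.1 at that rate), all of them the marker genes above. Those were taken up because their unevenness had been seen, and were checked on raw CPM where genes were checked on log2 CPM. The chance rate therefore cannot be applied to them. The lowest libraries were replicate 4 of 72 h for TR36823:c0_g1 (927 CPM), replicate 4 of 0 h for TR21098:c0_g1 (14.7), replicate 1 of 72 h for TR21334:c0_g1 (15.7), replicate 1 of 24 h for TR48898:c0_g1 (19.8), replicate 3 of 24 h for TR35250:c0_g1 (1.99) and replicate 4 of 24 h for TR22404:c0_g1 (0.388). The highest were replicate 1 of 24 h for TR9622:c2_g1 (12.3 CPM), replicate 2 of 24 h for TR48800:c18_g1 (0.456), replicate 2 of 72 h for TR40626:c2_g1 (422), replicate 4 of 0 h for TR23582:c0_g1 (0.0923, others 0), replicate 3 of 0 h for TR14963:c0_g1 (0.723, others 0), and for TR24867:c18_g1 replicate 4 of 24 h (0.129, others 0) and replicate 3 of 72 h (0.103, others 0).

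Of the genes named, 7 were called in opposite directions against 0 h at 2 times, with the difference tested in edgeR. From 14 h to 24 h the log2 change rose by 3.54 for TR21098:c0_g1 (photosystem II 12 kDa extrinsic protein), 5.46 for TR33524:c2_g1 (phosphoglycerate mutase), 6.31 for TR21449:c0_g1 (succinate dehydrogenase cytochrome b560), 0.81 for TR3356:c0_g1 (vacuolar iron transporter 1) and 1.97 for TR40626:c2_g1 (fucoxanthin-chlorophyll protein F), and it differed by -3.73 for TR34940:c0_g1 (condensin subunit 2). From 24 h to 72 h it rose by 1.24 for TR16475:c0_g1 (replication protein A). The largest edgeR adjusted p of these differences was 0.000197. The call of TR16475:c0_g1 at 72 h (0.41) was lost with RLE (0.28), with library size alone (0.07), and without replicate 2 (0.31) or 4 (0.35) of 0 h.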

How the results depend on the processing

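The alternatives without 3 vitellogenin-rich libraries, without arthropod-described genes and the TR39932 pair, and without list members matched by accident were chosen only after the data were seen. Counts are given in the order 14 h, 24 h and 72 h against 0 h, 24 h against 14 h, 72 h against 24 h. Of 98 alternative counts of genes, 93 lay within 1.5 times the reported count. With an adjusted p under 0.001 and at least 4-fold they were 12726, 9031, 4939, 3578 and 3396, fewer by construction. Leaving out 1 library gave 32266 to 36429, 30538 to 33109, 24596 to 26877, 15502 to 19513 and 20760 to 23010. Without the 3 vitellogenin-rich libraries, which leaves 1 library at 14 h that is assumed to vary like the other groups, they were 25867, 37840, 34504, 13449 and 25114, and without arthropod-described genes and TR39932 35038, 33570, 28564, 19335 and 24079. Camera with an estimated correlation called 0, 1, 4, 0 and 0 lists and fry 24, 23, 25, 23 and 18, and leaving out 1 library gave 8 to 11, 11 to 13, 10 to 12, 9 to 11 and 6 to 7. Culture number as a block ended the antioxidant call at 14 h and made plastocyanin (TR49637:c0_g1) called for 72 h against 24 h (0.28), and changed no other call of a named gene or list. Of 2858 alternative values of named genes 2804 kept direction and call, 35 lost the call and 8 gained it. The 11 that turned were near 0 or shifted by the scaling. TR49637:c0_g1 at 24 h had -0.06 with RLE, -0.4 with library size alone and -0.06 in DESeq2, and TR7137:c7_g1 -0.15, -0.49 and -0.15. TR7137:c7_g1 had 0.04 at 72 h without a filter and 0.12 for 72 h against 24 h with library size alone. TR49266:c0_g4 had 0.04 for 24 h against 14 h with library size alone, and leaving out 1 library gave -0.08 to 0.01 for TR7137:c7_g1 at 72 h (the highest without replicate 2 of 72 h) and -0.35 to 0.02 for TR35250:c0_g1 at 24 h (the highest without replicate 3 of 24 h). Without a filter the median was 0.61 for the chlorophyll list at 24 h and 0.43 for antioxidant enzymes at 72 h. Of 632 alternative camera tests of lists 567 kept the call and 65 lost it, 45 of them with an estimated correlation and 1, iron uptake for 24 h against 14 h, without members matched by accident (camera adjusted p = 0.537). The cause was not tested. The 3 overlaps kept their direction with the 0 h libraries divided. In simulated data, with far fewer genes changed, most 2-fold changes were missed.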

Other observations

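The test of paired descriptions and the words below were chosen only after the data were seen. Among 281 words in the descriptions, myosin genes, motors on actin, fell widely, with 85 of 115 lower and 7 higher at 14 h, 89 and 3 at 24 h, and 51 and 7 at 72 h (camera adjusted p = 5e-08, 2.14e-12 and 0.000216). These gave adjusted p = 0.479, 0.253 and 0.456 with an estimated correlation. Of 20 genes described with callose, a cell wall glucan, 17 were lower at 14 h, 18 at 24 h and 12 at 72 h, and 0, 0 and 1 higher (camera adjusted p = 0.439, 0.242 and 0.338 with an estimated correlation). Genes described with FKBP, a family of peptidyl-prolyl isomerases, were higher, with 22 of 41 at 14 h, 30 at 24 h and 27 at 72 h against 5, 2 and 2 lower (camera adjusted p = 0.361, 0.0262 and 0.0244 with an estimated correlation). Methyltransferases had 194 of 354 higher and 51 lower at 14 h, 206 and 38 at 24 h, and 106 and 46 at 72 h (camera adjusted p = 0.361, 0.171 and 0.353 with an estimated correlation). At 72 h 367 of 591 genes described as chloroplastic were higher and 61 lower (camera adjusted p = 0.0302 with an estimated correlation).

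The ribulose-phosphate 3-epimerases that moved apart raised the hypothesis that genes with the same description, word for word, were exchanged for each other more often than chance pairs them. At 14 h, 23 of 2633 descriptions with at least 2 genes held a gene at least 16-fold higher and another at least 16-fold lower. Shuffling the log2 changes over described genes 1000 times gave a mean of 23.2 such descriptions (12 to 39), so no exchange beyond chance was seen.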
